A study of Danio rerio with 2 samples.

How the data were processed

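The samples were 2 libraries of single cells from zebrafish larvae, 1 from a saline-injected and 1 from a UPEC-injected group. Per the labels' protocols, bodies without heads were dissociated with Liberase TL, passed through a 70 µm filter and depleted of dead cells with magnetic beads. The libraries were made with the Chromium Next GEM Single Cell 3' kit v3.1, per the labels' protocols. Per the submitters' processing notes, bcl2fastq, Cell Ranger 3.1, STAR and genome build GRCz11 were used. Their parameters and the annotation release were not given in the sources used here. The deposited values were raw UMI counts per gene and barcode, whole numbers without normalization, per the file headers and the values. Every deposited barcode held 500 or more UMIs, so the authors' choice of barcodes came before the steps below. The matrices held 28385 features under 27714 symbols, and counts of rows that shared a symbol were added, which left 671 fewer rows.

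Cells were kept with at least 300 genes and at most 20% mitochondrial UMIs. This left out 234 saline and 1947 UPEC barcodes under the gene minimum and 151 saline and 3248 UPEC barcodes over the mitochondrial limit, some of them on both grounds. Doublets were scored with Scrublet in each library, at expected rates of 2.25% and 17.5%. The automatic threshold called 2 saline barcodes and 0 UPEC barcodes. By a rule fixed in advance for a large library with almost no calls, the 3812 UPEC barcodes with the highest scores (17.5%) were then removed, so doublets were treated unlike in the 2 libraries. Kept cells of both libraries were clustered together without correction between libraries. UMIs were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 40 principal components, 15 neighbours and Leiden clustering at resolution 1 were used.

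Clusters were named from fixed markers of 32 cell classes. The naming rule was set after the data were seen. A cluster took the class with the highest mean marker fold against all other cells if at least 3 markers lay among its top 50 genes, at least 40% of detected markers stood at a log2 fold of 1 or more, no other class had more markers among the top 10 genes, and no other class with 5 or more detected markers had 80% of them at that fold. The rule named 24 clusters in 20 classes and left 10 clusters under numbers. A cluster high in both neutrophil and macrophage markers was split at Leiden resolution 0.1, a step also set after the data were seen.

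With 1 library per group, no test was made and cells were not used as replicates. UMIs were summed over the kept cells of a library or of a class with at least 20 cells in both libraries, which gave 9 classes, and divided by the sum to give CPM. Log2 ratios of UPEC over saline had 0.5 added to both counts and exact conditional 95% intervals. CPM had exact Poisson intervals and shares exact Clopper-Pearson intervals, all for counting error alone. A gene without a UMI in 1 library was given the bound that a floor of 3 UMIs allows. A fold given as at least some value is that bound, and the exact interval can reach lower. The median log2 ratio of all genes used genes with at least 30 UMIs in both libraries. The 25 fixed lists and 3 lists by symbol start were summarised as the median over members with at least 10 UMIs, with an order-statistic interval, where at least 5 members were measured. Members at least 1.5-fold higher or lower were counted, and the median was placed among 10000 random lists matched on expression in 20 bins. For the share of cells with a UMI, cells were thinned to 2200 UMIs, which left out 4 of 20 saline and 9 of 132 UPEC neutrophil-like cells and 1 of 12 saline and 77 of 237 UPEC macrophage-like cells.

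Genes were named by a rule fixed, like the lists, markers and comparisons, before the data were examined. In the whole libraries, the neutrophil-like class and the largest other class by saline cells (superficial epidermis-like), the rule named the first 10 genes in each direction by the interval bound nearest 0. Such a gene had a log2 ratio of at least 1 in size, at least 30 UMIs, a UMI in at least 10 cells of the higher library and no cell with over 25% of its UMIs there. Within a class its CPM was at least 0.5 times that of the whole library, which left out free RNA from other cells. Mitochondrial, ribosomal and clone-based names were left out, and 1 gene that the rule named as lower in the whole libraries is not reported here. The rule further named up to 4 of the most abundant members of each described list and 20 preset immune genes in neutrophil-like and macrophage-like cells. The same ranking in lymphocyte-like, enterocyte-like and fibroblast-like cells was chosen after their values were seen. Hepatocyte-like cells had no saline cell, and macrophage-like cells were below the minimum of 20, so neither was ranked.

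The method was tested on simulated data made from these libraries with known ratios. Summed counts were drawn with counting error alone, the error that the intervals assume. The share of intervals holding the true ratio was therefore largely fixed by design. It does not bear on UMIs clumped in few cells or on differences between libraries. The naming thresholds were scored on these summed counts, without the rules on cells and free RNA. Intervals held the true ratio for 95.7% of 18773 genes in the whole libraries, 97.1% of 4952 genes in the neutrophil-like class and 96.0% of 9089 genes in the superficial epidermis-like class. In each, 20 of 20 lists with a built-in shift lay above the 97.5th percentile, and 3, 4 and 6 of 100 lists without a shift lay outside the central range. Of genes with a built-in log2 ratio of 2, the naming thresholds recovered 98.5%, 63.6% and 98.5%, and of those with 1, they recovered 38.2%, 22.1% and 54.4%. Genes without a shift passed them in 107, 89 and 73 cases.

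Alternatives tried were at least 500 genes per cell, at most 10% mitochondrial UMIs, doublets kept, Leiden resolution 2, genes scaled within each library, UPEC cells drawn to the saline number, median-of-ratios scaling, the mean of the cells' own CPM, 5 added to both counts, list members with at least 30 UMIs, free-RNA members left out, each class weighted equally and cells not thinned. Chosen after seeing the data were unnamed clusters joined to the class of their highest markers, no barcode over 50000 UMIs, shares among cells not erythroid-like, scaling within each library for the lists, and members at their bound. RNA velocity and canonical pathway analysis, which the series describes, were not used here, since the matrices used here hold no separate spliced and unspliced counts and no pathway database was at hand. The tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5 with its Scrublet, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9.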

Results

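The data were single-cell transcriptomes of zebrafish larvae injected with bacteria or with saline. Uropathogenic Escherichia coli (UPEC), strains that cause most urinary tract infections and can spread to the blood, were placed in the pericardial cavity, the fluid space around the heart. Larvae of about 4 days received about 1 nl of a mixture with or without bacteria, in groups of about 30. The bodies, without heads, were dissociated 24 hours later, at an age of 5 days. The question was how the cells of the body, and those of innate immunity above all, differed between infected and control larvae. Each group gave 1 library, so differences between the groups had no replicate check and no test was possible. Intervals of list medians below are order-statistic intervals over the members, and every other interval covers counting error alone. The saline library held 2810 barcodes and 24368231 UMIs, with a median of 4315 UMIs and 1002.5 genes per barcode. The UPEC library held 21830 barcodes and 148303858 UMIs, with a median of 3374.5 UMIs and 709 genes. After filters on genes, mitochondrial UMIs and doublets, 2507 saline and 14788 UPEC cells were kept, with median depths of 5171 and 4110.5 UMIs.

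The first comparison asked which cell types the libraries held. Cells with the profile of superficial epidermis, the outer skin layer, dominated the saline library and were scarce in the UPEC library. Erythroid-like cells, the red blood cell lineage, took the place of the largest class in the UPEC library. Macrophage-like cells, tissue phagocytes, and lymphocyte-like cells had higher shares in the UPEC library. Neutrophil-like cells, phagocytes that reach an infection early, had about the same share of all kept cells in both.

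Superficial epidermis-like cells made up 41.1% (39.2% to 43.0%) of saline cells and 1.58% (1.38% to 1.79%) of UPEC cells, a share 26.1-fold lower in UPEC. The log2 ratio of the shares was -4.70 (-4.92 to -4.50). It was -2.49 when genes were scaled within each library before clustering and -2.56 with unnamed clusters joined to the class of their highest markers. Basal epidermis-like cells, the layer below, made up 9.85% (8.71% to 11.09%) and 3.104% (2.83% to 3.40%). Erythroid-like cells made up 16.8% (15.3% to 18.3%) of saline and 42.9% (42.1% to 43.7%) of UPEC cells, a log2 ratio of 1.35 (1.21 to 1.497). It was 2.27 with at least 500 genes per cell, 2.09 at Leiden resolution 2 and 0.83 with no barcode over 50000 UMIs. Cluster 00 held 96.7% of the saline cells of that class, whereas clusters 12, 24 and 13 held 49.7%, 26.7% and 23.4% of the UPEC cells. Lymphocyte-like cells stood at 1.48% (1.04% to 2.03%) and 2.41% (2.17% to 2.67%), and macrophage-like cells at 0.479% (0.248% to 0.835%) and 1.60% (1.41% to 1.82%). Neutrophil-like cells stood at 0.798% (0.488% to 1.23%) and 0.893% (0.747% to 1.06%), a difference within counting error among all kept cells. Fibroblast-like cells stood at 7.10% and 6.51% and skeletal muscle-like cells at 1.83% and 1.95%, also within it among all kept cells. Enterocyte-like cells, the absorptive lining of the gut, stood at 4.23% (3.47% to 5.09%) and 2.13% (1.90% to 2.38%). Chondrocyte-like cells stood at 5.46% and 4.105%, a log2 ratio of -0.41 (-0.68 to -0.13). The shares depend on the other classes in the denominator, and they were computed again without erythroid-like cells. Among the other cells, the log2 ratio was 0.70 for neutrophil-like cells, at 0.959% (0.587% to 1.48%) and 1.56% (1.31% to 1.85%), and fibroblast-like cells turned to 0.42, at 8.53% (7.37% to 9.82%) and 11.4% (10.7% to 12.1%). It was 0.63 for skeletal muscle-like, 0.13 for chondrocyte-like, 1.25 for lymphocyte-like, -0.45 for enterocyte-like and -1.12 for basal epidermis-like cells. Superficial epidermis-like cells made up 49.4% (47.2% to 51.5%) of these saline cells and 2.76% (2.42% to 3.13%) of these UPEC cells. The ratios of the other classes therefore rest on that class too, and shares without it were not computed. Hepatocyte-like cells numbered 0 of 2507 in saline, which allows a share of up to 0.147%, and 45 in UPEC, at 0.304% (0.222% to 0.407%). The lower bound of their log2 share ratio was 0.99.

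Melanophore-like cells, the black pigment cells, made up 0.558% (0.306% to 0.935%) of saline and 2.00% (1.78% to 2.24%) of UPEC cells. Iridophore-like cells, the reflective pigment cells, made up 0.399% and 1.29%, and goblet or mucous-like cells 0.558% and 1.60%. The 10 clusters without a name held 7.78% of saline and 24.5% of UPEC cells. Cluster 20, nearest to superficial epidermis by its markers, held 0.279% of saline and 5.43% of UPEC cells, and cluster 25, nearest to basal epidermis, held 0.199% and 4.88%. Cluster 10, nearest to fibroblasts, held 0.399% and 2.79%, and cluster 09, nearest to the erythroid class, held 1.28% and 5.88%. A threshold set after the data were seen kept such clusters out of the named classes, so the shares of the epidermal, fibroblast and erythroid classes rest on it. Effects of dissociation and dead cell removal on these shares were not tested, and a cluster found mostly in 1 library can be a property of that library.

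**Figure D1:**
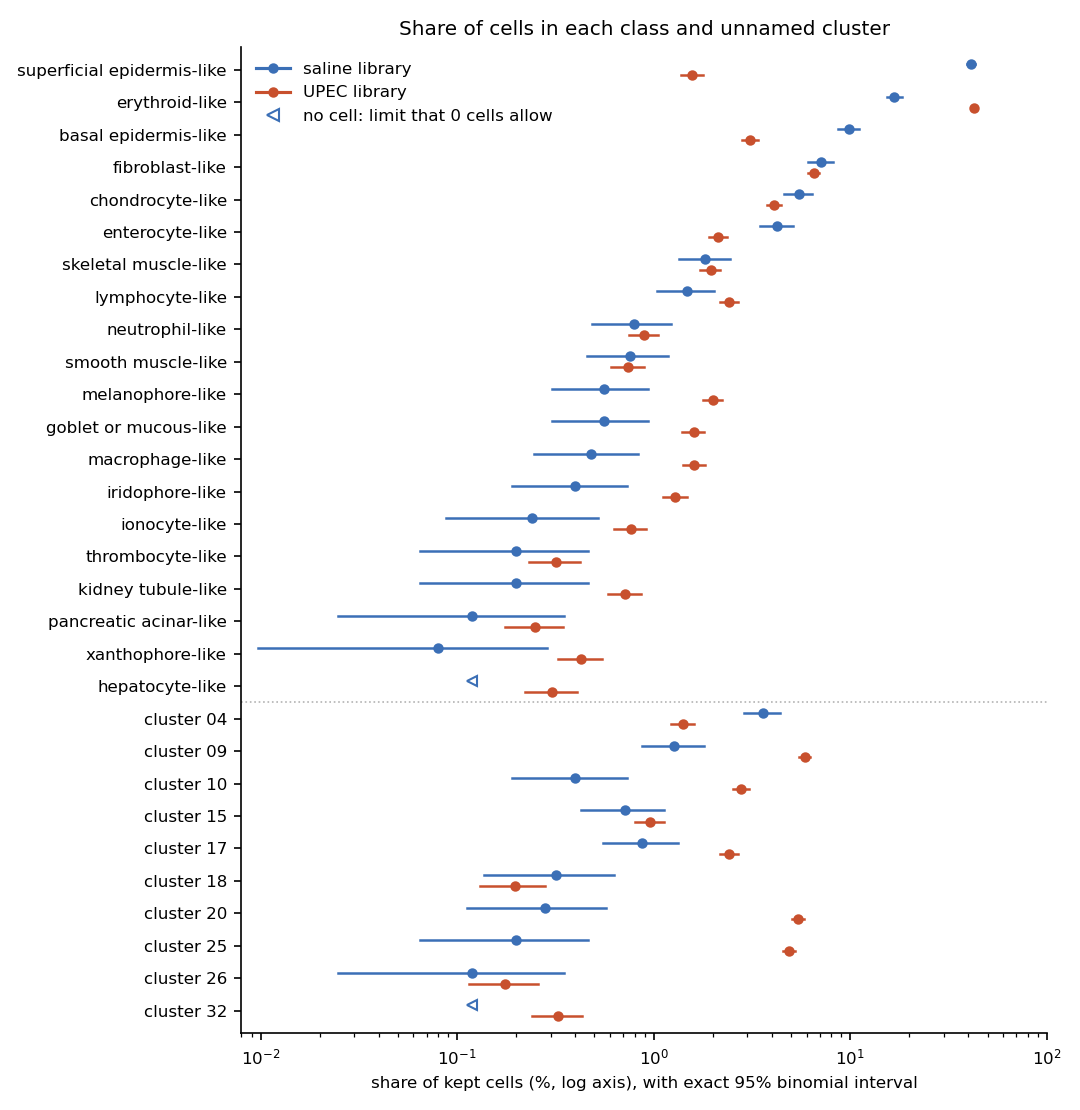
Share of kept cells in each named class (top) and unnamed cluster (bottom), in percent on a log axis, for the saline library (blue, 2507 cells) and the UPEC library (orange, 14788 cells), with bars for exact 95% binomial intervals and open triangles at the share of 3 cells where a library had none. Superficial epidermis-like cells stand at 41.1% in saline and 1.58% in UPEC, and neutrophil-like cells at 0.798% and 0.893%.

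The second comparison summed the UMIs of all kept cells in each library, to describe the larval body as a whole. Transcripts of the acute phase, the set of plasma proteins that the liver and other tissues release in infection, stood far higher in the UPEC library. Complement, the plasma cascade that coats and lyses bacteria, stood higher too, as did cytokines, chemokines and antibacterial effectors. Such sums also follow which cells a library held, and hepatocyte-like cells numbered 0 in saline and 45 in UPEC. Transcripts of the outer epidermis stood lower. Genes of the immediate early and dissociation stress list, which react within minutes to handling, stood lower in UPEC by their median, with an interval that reached no difference. Within classes, their median stood higher in UPEC in 5 of 9. The median log2 ratio over all 12603 genes with 30 or more UMIs in both libraries was 0.13, against which these values are read.

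The acute phase list had a median log2 ratio of 4.14 (2.69 to 5.07) over 37 measured members, of which 31 were at least 1.5-fold higher and 2 at least 1.5-fold lower. Serum amyloid A, saa, stood at 4.78 CPM (3.94 to 5.74) in saline and 143 CPM (141 to 145) in UPEC, a log2 ratio of 4.90 (4.64 to 5.18). The leukocyte chemotaxin lect2l stood at 31.7 and 285 CPM, whereas the transcription factors cebpb and cebpd had log2 ratios of -0.08 and -0.44. In the complement list, 30 of 37 members were higher and 0 lower, with a median of 2.53 (1.87 to 3.64). The central component c3a.1 stood at 0.880 CPM (0.545 to 1.34) and 40.9 CPM (39.8 to 42.1), and factor D, cfd, at 50.1 and 96.7 CPM. Among cytokines and chemokines, 27 of 42 members were higher and 6 lower, with a median of 1.81 (0.52 to 2.65). The pyrogenic cytokine il1b stood at 112 CPM (108 to 116) and 442 CPM (438 to 445), a log2 ratio of 1.98 (1.92 to 2.04). The chemokine cxcl18b had a log2 ratio of 1.87 (1.80 to 1.94), while the neutrophil attractant cxcl8a had -0.29 (-0.31 to -0.26) and the prostaglandin synthase ptgs2b -1.47 (-1.50 to -1.43). Antibacterial effectors had a median of 1.74 (1.15 to 2.44), with 21 of 28 higher and 4 lower, and included lysozyme, lyz, at 169 and 1342 CPM and the collagenase mmp13a at 232 and 1276 CPM. With members lacking a UMI in 1 library placed at their bound, the medians were 4.06 for acute phase, 2.34 for complement, 1.49 for cytokines and 1.33 for antibacterial effectors. Each of these 4 medians lay above all 10000 matched random lists, as a description of these libraries. The acute phase members tfa, fgg and fgb were also markers of the hepatocyte-like class, and c9, a member of both the acute phase and complement lists, led its cluster. The random lists were matched on expression and not on cell type. For acute phase and complement, the rank can therefore reflect hepatocyte-like cells found in UPEC alone.

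Most genes named by the fixed rule lay mainly in 1 class or cluster. Of the 10 named as higher in UPEC, 7 had 82.9% to 95.1% of their UPEC UMIs in the 45 hepatocyte-like cells. These were the liver fatty acid binding protein fabp10a, complement factor B (cfb), the terminal complement component c9, the fibrinogen chain fgb, the apolipoproteins apoa1b and apoa2, and the esterase ces2a. There were 2 UMIs of fabp10a in saline and 15067 in UPEC, a log2 ratio of 10.29 (8.76 to 13.66). There were 0 UMIs of cfb in saline and 2316 in UPEC, at least 160-fold higher. The parvalbumin pvalb9 lay mostly in kidney tubule-like cells (90.7% of UPEC UMIs) and the protease inhibitor spink2.5 in cluster 26 (98.6%). The cytokine tnfa, a central signal of bacterial infection, had 3 UMIs in saline and 2439 in UPEC, a log2 ratio of 7.18 (5.85 to 9.68), and cluster 25 held 69.4% of the UPEC UMIs. Of the genes named as lower, krt1-19d, a keratin, lay in goblet or mucous-like cells (99.3% of its saline UMIs) and had a log2 ratio of -6.76 (-7.13 to -6.42), although these cells had the higher share in UPEC. The other 8 given here had 81.5% to 98.2% of their saline UMIs in superficial epidermis-like cells. These were tgm5l, a transglutaminase-like gene, rbp7a, mala, dhrs13a.2, abcc6b.2, ponzr4 and the epidermal calcium-binding genes icn and icn2. The gene icn stood at 12752 and 959 CPM, a log2 ratio of -3.73 (-3.74 to -3.72). With equal weight for each of the 9 classes that had 20 cells in both libraries, which leaves out hepatocyte-like and goblet or mucous-like cells, the medians were 1.65 for acute phase, 1.68 for complement, 0.85 for cytokines and chemokines and 0.17 for antibacterial effectors. Over the 22 cytokine members with 30 or more saline UMIs, the whole-library median was 0.94.

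Inflammatory transcripts lay in different clusters in the 2 libraries, and cluster 25, nearest to basal epidermis, was kept out of that class by the naming rule. In saline, basal epidermis-like cells held 90.6% of the cxcl8a UMIs and 54.6% of the il1b UMIs, and superficial epidermis-like cells held 87.8% of ptgs2b. In UPEC, cluster 25 held 59.9% of cxcl8a, 49.1% of il1b and 52.2% of ptgs2b. Of the 13 basal epidermis markers detected, 1 lay among the top 50 genes of cluster 25, and 38.5% stood at a log2 fold of 1 or more. The leading genes of cluster 25 included the metalloproteinases mmp9 and mmp13a and the hyaluronan receptor cd44a. Its leading genes mmp9, mmp13a and scpp8 were markers of the neutrophil class, so its identity stays open. In saline, basal epidermis-like cells held 84.9% of the mmp9 UMIs and 81.0% of the mmp13a UMIs.

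The remaining lists are given over the whole libraries as median log2 ratios. Neutrophil granule and migration genes stood at 1.46, coagulation at 1.35, glycolysis at 1.12, phagocytic receptors and uptake at 1.098 and MHC class II presentation at 1.00. Iron handling stood at 0.79, phagocyte oxidase at 0.76, cell cycle at 0.62, lipid and lipoprotein at 0.59, interferon response at 0.51, JAK-STAT and SOCS at 0.51 and lysosome and proteolysis at 0.47. The lists for NF-kB feedback (0.26), inflammasome and pyroptosis (0.25), ER stress (0.15), p53 and apoptosis (0.15), ribosomal proteins (0.12), Toll-like and NOD receptors (0.10), tissue repair (0.08), mitochondrially encoded genes (0.07) and nuclear oxidative phosphorylation (0.06) lay near the median of all genes. Oxidative stress stood at -0.03, glucocorticoid response at -0.08 and immediate early and dissociation stress at -0.50 (-0.69 to 0.01), the 1.96th percentile of matched lists.

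**Figure D2:**
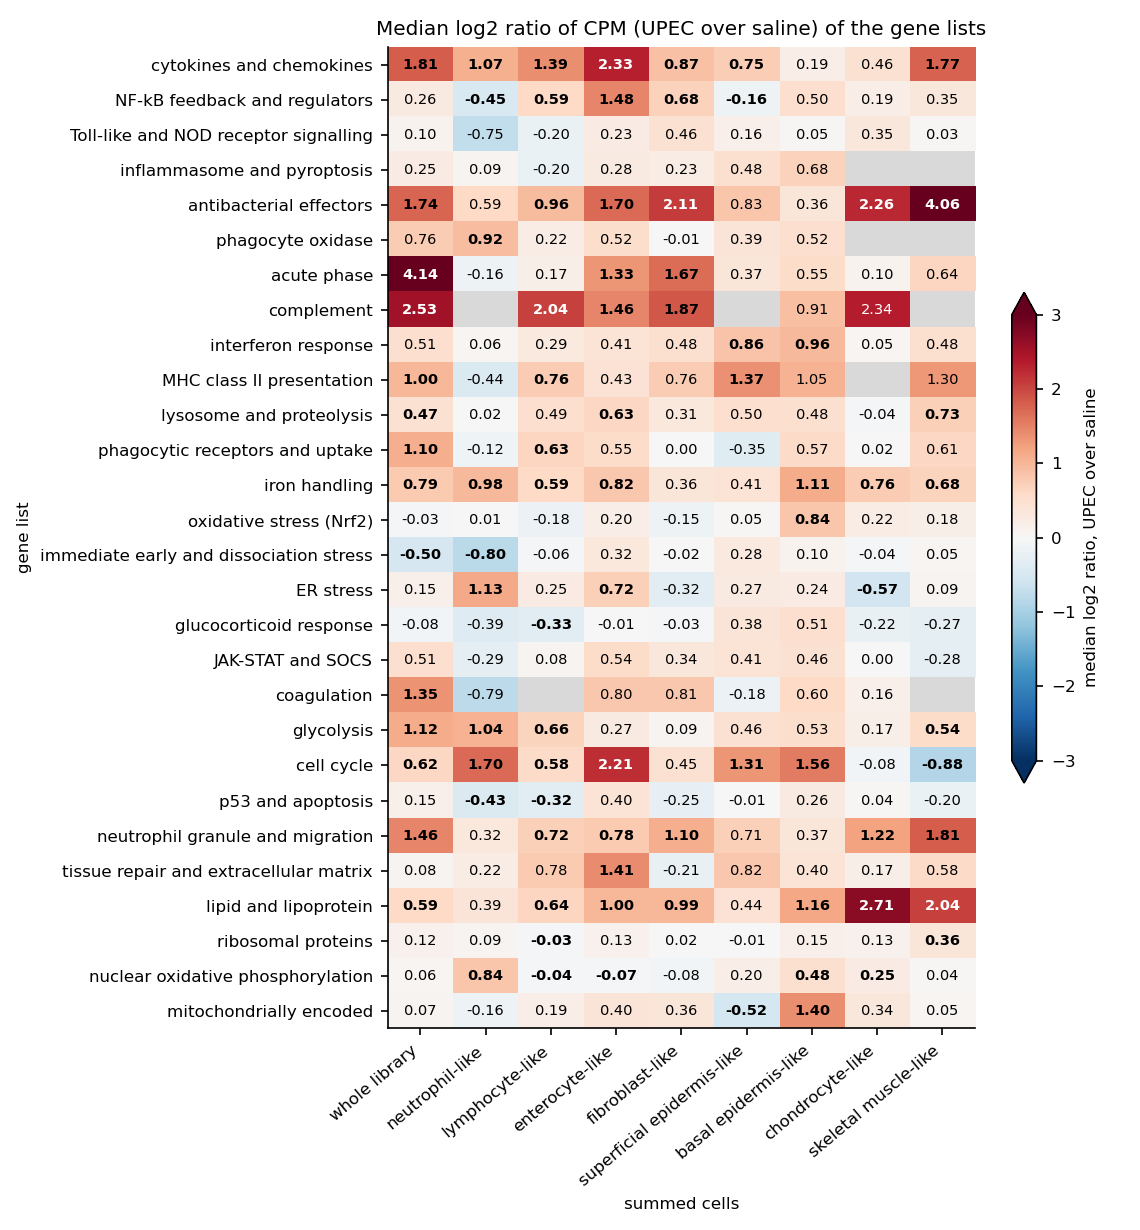
Median log2 ratio of CPM, UPEC over saline, of the 28 gene lists (vertical axis) in the whole libraries and in 8 cell classes (horizontal axis), with red for higher and blue for lower in UPEC, bold type for values outside the central 95% of matched random lists, and grey for lists with under 5 measured members. Cytokines and chemokines range from 0.19 in basal epidermis-like to 2.33 in enterocyte-like cells.

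The third comparison looked within the neutrophil-like class, with 20 saline and 132 UPEC cells. The disulfide isomerase pdia6, the chaperones calr and calr3b, the dehydrogenases ldhba, bdh1 and mdh1aa, and chromatin and tubulin genes of the cell cycle list stood higher in neutrophil-like cells of the UPEC library. Many immediate early genes and the NF-kB inhibitors nfkbiaa and nfkbiab stood lower. The collagenases mmp9 and mmp13a stood lower, lysozyme stood higher, and il1b stood nearly level. The cells of the 2 libraries differed in depth, with medians of 4979.5 and 14932.5 UMIs. The median log2 ratio of all genes in this class was -0.11.

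The 10 genes named as higher were pdia6, ndufa4, ldhba, calr3b, bdh1, hsp90aa1.2, mdh1aa, calr, atp5f1b and lygl1. The disulfide isomerase pdia6 stood at 36.2 CPM (11.7 to 84.4) and 485 CPM (457 to 514), a log2 ratio of 3.61 (2.52 to 5.37). The calcium-binding chaperone calr3b stood at 72.3 and 624 CPM, a log2 ratio of 3.04 (2.22 to 4.17), and the lactate dehydrogenase ldhba at 43.4 and 472 CPM, 3.33 (2.32 to 4.89). The respiratory subunit ndufa4 had 0 UMIs in saline and 323 in UPEC, at least 6.43-fold higher, and the ketone dehydrogenase bdh1 had 0 and 258, at least 5.13-fold higher. The 10 named as lower were rnf128a, scpp8, mhc1zba, tnfrsf1b, slc7a3a, sult5a1, ppt1, smox, antxr2a and mmp9. The ubiquitin ligase rnf128a had a log2 ratio of -3.37 (-4.37 to -2.28), the TNF receptor tnfrsf1b -2.55 (-3.42 to -1.53) and the MHC class I gene mhc1zba -2.24 (-2.66 to -1.79). The genes scpp8, antxr2a and mmp9 were also leading genes of cluster 25.

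By list, 35 of 40 cell cycle members were higher and 0 lower in the neutrophil-like class, with a median of 1.70 (1.47 to 2.41), and 1.27 with the 12 members lacking a UMI in saline at their bound. Its most abundant members were hmgn2 (1.26), hmgb2a (1.27), h2az2b (0.71) and tubb2b (1.28). The median was 0.94 when genes were scaled within each library before clustering. Of 28 ER stress members, 18 were higher and 5 lower, with a median of 1.13 (-0.02 to 1.81), and 0.95 with members at their bound. The ER chaperone hspa5 stood at 311 and 1101 CPM, a log2 ratio of 1.81 (1.39 to 2.29), with hsp90b1 at 2.15, pdia3 at 1.65 and xbp1 at 0.65. Nuclear oxidative phosphorylation had 52 of 87 members higher and 5 lower, with a median of 0.84 (0.52 to 1.14), and glycolysis 13 of 23 higher and 3 lower, with a median of 1.04 (-0.34 to 1.38). Of the abundant glycolytic genes, gapdhs (1.11), eno3 (1.19) and pgk1 (1.04) stood higher and gapdh (-0.41) lower. Cytokines and chemokines had 11 of 18 higher and 3 lower, with a median of 1.07 (-0.03 to 2.16) and 0.70 at the bound. The cytokine il34 stood at 203 and 456 CPM and the granulocyte growth factor csf3b at 210 and 426 CPM, whereas tnfb stood level at -0.03. Of 41 immediate early genes, 23 were lower and 3 higher, with a median of -0.80 (-1.39 to -0.37), below all 10000 matched lists. NF-kB feedback genes had 8 of 20 lower and 1 higher, with a median of -0.45 (-0.81 to -0.12). The NF-kB inhibitor nfkbiab stood at 3906 CPM (3584 to 4250) and 2227 CPM (2167 to 2289), and nfkbiaa at 1635 and 808 CPM, while birc2 (-0.20) and nfkbie (-0.04) differed little.

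The log2 ratios of preset immune genes were read in the neutrophil-like class whatever their values. For cxcl8a it was -2.21 (-3.05 to -1.21), but the 14 saline UMIs came from 3 of 20 cells, and the share of cells with a UMI was 12.5% and 4.88% thinned and 15% and 18.2% unthinned. The log2 ratio was -1.62 (-1.80 to -1.43) for mmp9, -1.41 (-1.52 to -1.29) for mmp13a, -1.24 (-2.04 to -0.24) for the growth factor receptor csf3r and -3.01 (-4.45 to -1.27) for saa. It was 1.19 (1.15 to 1.24) for lyz, 0.76 (0.64 to 0.90) for npsn and 0.41 (0.27 to 0.56) for mpx. These granule genes are markers that define the class, and so are mmp9, mmp13a and scpp8, which stood lower. For il1b the log2 ratio was 0.30 (0.15 to 0.46), and for cebpb 0.37 (0.17 to 0.58), but -0.04 and -0.16 when each cell counted equally. After thinning to 2200 UMIs, 87.5% (61.7% to 98.4%) of 16 saline and 56.1% (46.9% to 65.0%) of 123 UPEC cells had a UMI of mmp9, and 95% and 75.8% of all cells of the class did unthinned. The share with il1b was 93.8% and 91.1% thinned, and 95% and 92.4% unthinned. The thinned share was 62.5% and 71.5% for nfkbiaa and 93.8% and 84.6% for lyz. Both ran against the direction of the CPM, with overlapping intervals. In skeletal muscle-like cells, which should lack il1b and mmp9, 0 of 45 saline cells (up to 7.87%) and 2.96% of 270 UPEC cells had il1b, and 0 of 45 and 1.85% had mmp9. Those cells had median depths of 19778.5 and 18222 UMIs. The saline values of this class rest on 20 cells and 138231 UMIs.

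Macrophage-like cells numbered 12 in saline and 237 in UPEC, below the minimum of 20 for lists, so only the preset genes were read. The cytokine tnfa and mmp9 stood higher in UPEC, il1b stood level and cxcl8a stood lower. The gene tnfa had 1 UMI in saline and 398 in UPEC, at 5.32 CPM (0.135 to 29.6) and 108 CPM (97.3 to 119), a log2 ratio of 3.76 (1.85 to 9.65). After thinning, 0 of 11 saline cells, which allows up to 28.5%, and 13.1% (8.31% to 19.4%) of 160 UPEC cells had a UMI of tnfa, and 8.33% and 24.5% did unthinned. The share was 0.370% in UPEC skeletal muscle-like cells. The log2 ratio was 2.54 (1.45 to 4.31) for mmp9, 0.10 (-0.05 to 0.26) for il1b and -0.86 (-1.03 to -0.69) for cxcl8a. For the iron regulator hamp, 1 saline UMI stood against 310 UPEC UMIs from 21 of 237 cells, but the unthinned share of cells with a UMI was 8.33% and 8.86%, and 7.64% in UPEC skeletal muscle-like cells. The neutrophil marker mpx had 17 and 629 UMIs, a log2 ratio of 0.87 (0.22 to 1.70), and npsn had 0 and 48 UMIs, while the 83 saline UMIs of lyz came from 1 cell. The macrophage and neutrophil classes were parted by a split of 1 cluster that was set after the data were seen.

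**Figure D3:**
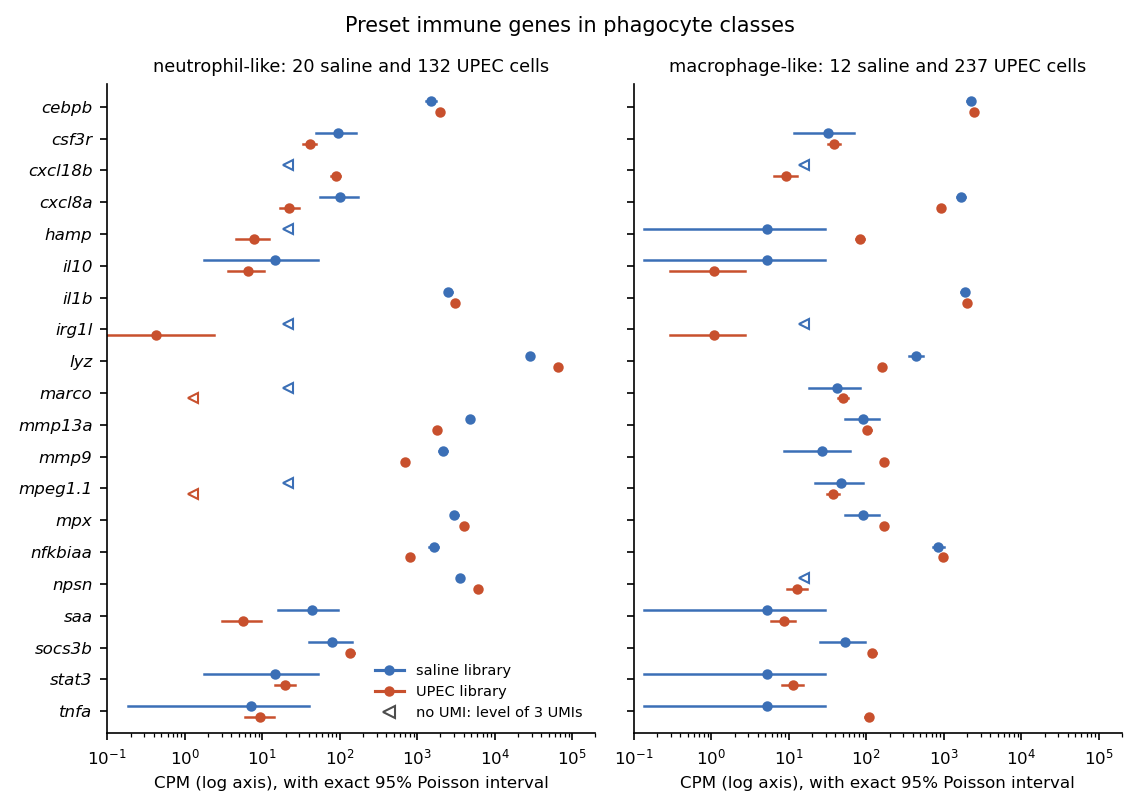
CPM on a log axis of the 20 preset immune genes in neutrophil-like cells (left) and macrophage-like cells (right), for the saline library (blue) and the UPEC library (orange), with bars for exact 95% Poisson intervals and open triangles at the level of 3 UMIs where a library had none. In neutrophil-like cells mmp9 stands at 2134 CPM in saline and 696 CPM in UPEC, and in macrophage-like cells tnfa stands at 5.32 and 108 CPM.

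The same comparison was made in lymphocyte-like cells, 37 in saline and 357 in UPEC. By the rule of the neutrophil class, applied here after the values were seen, the genes ranked first included the costimulatory receptors tnfrsf9b, tnfrsf9a and tnfrsf18, the chemokine ccl35.1 and the death ligand faslg. The gene ccl35.1 was also a leading gene of the macrophage-like cluster. In UPEC, macrophage markers stood in this class at 2.99% of their level in macrophage-like cells, the highest of the 8 classes compared. The gene tnfrsf9b, a marker of the class and a leading gene of its cluster, stood at 32.1 and 442 CPM, a log2 ratio of 3.72 (2.98 to 4.74). There were 0 and 251 UMIs of tnfrsf18, at least 6.26-fold higher, and 1 and 267 UMIs of faslg, a log2 ratio of 3.74 (1.83 to 9.63). The chemokines ccl20a.3 and ccl38.6, which also led the cluster, stood at 294 and 892 CPM and at 281 and 751 CPM. Of 26 cytokine and chemokine members, 17 were higher and 6 lower, with a median of 1.39 (-0.30 to 2.33), but 0.26 with the 9 members lacking a UMI in 1 library at their bound. Here il1b ran the other way, at 219 and 87.2 CPM.

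In enterocyte-like cells, 106 in saline and 315 in UPEC, the medians of the inflammatory lists stood higher in UPEC. The interval of the cytokine and chemokine list held 0. The inflammatory lists held il1b, the antibacterial itaconate gene irg1l, acute phase genes and the inhibitors of NF-kB. Proliferation genes stood higher as well. Cytokines and chemokines had 14 of 19 members higher and 3 lower, with a median of 2.33 (-0.05 to 5.65) and 1.68 at the bound. There were 4 UMIs of il1b in saline and 1036 in UPEC, from 92 cells, a log2 ratio of 5.65 (4.46 to 7.70). The chemokine ccl20a.3 had 0 and 514 UMIs, at least 37.3-fold higher, from 15 UPEC cells. NF-kB feedback genes had 18 of 20 higher and 0 lower, with a median of 1.48 (1.103 to 2.41) and 1.12 at the bound, and nfkbiab stood at 418 and 1389 CPM, with relb at 1.98, nfkbiaa at 0.82 and tnip1 at 0.71. The gene irg1l stood at 93.0 CPM (71.1 to 119) and 579 CPM (552 to 607), a log2 ratio of 2.63 (2.27 to 3.03), and the collagenase inhibitor timp2b ran the other way at -1.89. Acute phase genes had 18 of 24 higher and 3 lower, with a median of 1.33 (0.62 to 3.09) and 0.75 at the bound. Of 40 cell cycle members, 35 were higher and 2 lower, with a median of 2.21 (1.47 to 3.16) and 1.45 at the bound. The proliferation marker mki67 had 1 and 171 UMIs, a log2 ratio of 4.64 (2.72 to 10.53). Epidermal genes differed within this class too, with icn at 46034 and 4781 CPM and krt5 at 114 and 952 CPM. In both libraries icn stood higher in this class than in the whole library, so the class need not hold absorptive gut cells alone. Unlike make-up of the class in the 2 libraries can therefore enter each of these ratios. The median mitochondrial share of its cells was 0.591% in saline and 3.14% in UPEC.

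Fibroblast-like cells, 178 in saline and 963 in UPEC, had the acute phase gene saa higher in UPEC. The acute phase list as a whole had an interval that held 0. The gene saa had 11 UMIs in saline and 4468 in UPEC, at 13.1 CPM (6.53 to 23.4) and 997 CPM (968 to 1026), a log2 ratio of 6.19 (5.41 to 7.26). Of 14 acute phase members, 9 were higher and 2 lower, with a median of 1.67 (-0.44 to 4.16), but the abundant members cebpd (0.17), cebpb (-0.29) and il6st (-0.44) did not share the level of saa. Genes ranked first by the same rule, again applied after the values were seen, included the interferon-induced ifitm1, with 0 and 4198 UMIs (at least 263-fold higher), and hamp, with 0 and 175 UMIs (at least 10.9-fold higher). The genes saa, ifitm1 and hamp were also leading genes of cluster 10, which was nearest to this class and held 55.1% of the UPEC UMIs of saa. The fin fold gene and1, a marker of the class, stood at 4392 and 562 CPM. Cluster 02, led by the amino acid catabolism genes hpdb, tat, pah and hgd together with col1a1a, held 50.6% of the saline cells of this class, and cluster 08, led in part by the chemokine genes ccl25b and cxcl12a, held 69.6% of the UPEC cells. The median log2 ratio of all genes in this class was -0.17.

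The epidermal classes were compared next. In superficial epidermis-like cells, 1030 in saline and 233 in UPEC, the cell cycle list and the interferon response stood higher in UPEC. MHC class II presentation had a median above 0 with an interval that held 0. Arginase and the metabolic regulator foxo1a stood lower. Of 42 cell cycle members, 37 were higher and 0 lower, with a median of 1.31 (0.94 to 1.49), and the histone h2az2b stood at 95.1 and 238 CPM. MHC class II presentation had a median of 1.37 (-0.80 to 1.92), with 7 of 11 higher and 2 lower, and the protease ctss2.2 stood at 57.1 and 147 CPM. The interferon response had a median of 0.86 (0.49 to 1.67), with 18 of 31 higher and 4 lower. The genes named as higher were sesn1, krt96, plekhs1, ccl20a.3, ms4a17a.12, ninl, ccnd2a, mtus1b, gins3 and mhc1lla. The stress-induced sestrin sesn1 stood at 5.01 and 107 CPM, a log2 ratio of 4.402 (4.02 to 4.83), the chemokine ccl20a.3 at 8.26 and 85.9 CPM, 3.37 (3.05 to 3.72), and the cyclin ccnd2a at 4.39 and 41.2 CPM. The genes named as lower were npb, cspg5b, arg2, clec19a, atp1b1b, abcc6b.2, foxo1a, acsl4b, nfil3-6 and fam89a. The arginase arg2 stood at 459 CPM (447 to 472) and 37.7 CPM (32.5 to 43.4), a log2 ratio of -3.60 (-3.82 to -3.40), and foxo1a at 304 and 30.2 CPM. The median log2 ratio of all genes in this class was 0.32, and its cells had median depths of 9035.5 and 21410 UMIs.

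Basal epidermis-like cells, 247 in saline and 459 in UPEC, also had cell cycle genes higher, 36 of 41 with 0 lower and a median of 1.56 (1.23 to 2.69). The iron handling list had a median of 1.11 (0.26 to 1.97), with 13 of 24 higher and 1 lower, whereas the ferritin fthl27, which stores iron, stood at 4913 and 3341 CPM. The interferon list had a median of 0.96 (0.26 to 1.34), with 16 of 25 higher and 4 lower, yet its most abundant members ran the other way, with ifi45 at 371 and 92.9 CPM and the regulator irf7 at 113 and 37.8 CPM. The median log2 ratio of all genes in this class was 0.24, its cells had median depths of 10209 and 3747 UMIs, and their median mitochondrial shares were 0.985% and 2.64%.

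Structural and blood classes were compared last. In chondrocyte-like cells, the cartilage class, 137 in saline and 607 in UPEC, ER stress genes stood lower, 11 of 24 with 1 higher and a median of -0.57 (-0.93 to -0.30), against -0.22 for all genes of the class. The 4 abundant members differed less, or the other way, with xbp1 at 0.11, ddit3 at -0.05, atf4b at -0.30 and the glutathione-degrading chac1 at 0.76. In skeletal muscle-like cells, 46 in saline and 288 in UPEC, 20 of 32 cell cycle members were lower and 2 higher, with a median of -0.88 (-1.64 to -0.41), but 0.02 when each cell counted equally. In erythroid-like cells, 421 in saline and 6338 in UPEC, all 44 cell cycle members were lower, with a median of -2.63 (-2.86 to -2.40). That value followed the clusters that held the class in each library, and was 0.67 at Leiden resolution 2 and 0.56 with genes scaled within each library.

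**Figure D4:**
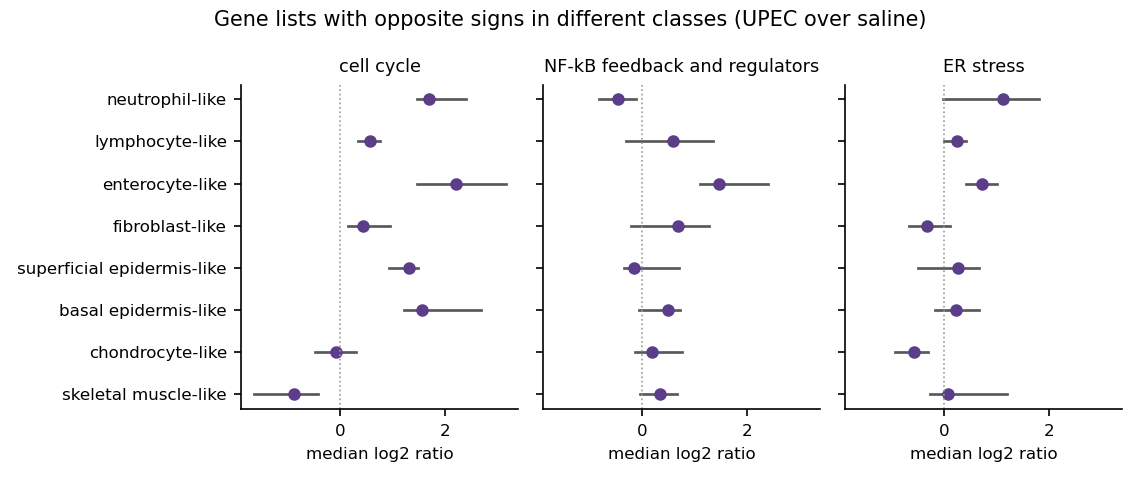
Median log2 ratio, UPEC over saline, of the cell cycle, NF-kB feedback and ER stress lists (horizontal axis) in 8 cell classes (vertical axis), with bars for 95% order-statistic intervals over the list members. Cell cycle stands at 2.21 in enterocyte-like and -0.88 in skeletal muscle-like cells, NF-kB feedback at 1.48 in enterocyte-like and -0.45 in neutrophil-like cells, and ER stress at 0.72 in enterocyte-like and -0.57 in chondrocyte-like cells.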

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

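The tests of unnamed clusters and of dilution by erythroid-like cells were chosen only after the result was seen, and the others here before.

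A list was counted as differing in opposite directions where each of 2 classes had an interval that left out 0 and a percentile beyond the central 95%, one higher and one lower. Erythroid-like cells were left out of this count because different clusters held the class in the 2 libraries. This gave 2 lists, and cell cycle genes in the summed UMIs alone, and the difference between classes was not tested. NF-kB feedback genes, which restrain inflammatory signalling, had a median log2 ratio of 1.48 in enterocyte-like and -0.45 in neutrophil-like cells. ER stress genes stood at 0.72 in enterocyte-like and -0.57 in chondrocyte-like cells, and cell cycle genes at 2.21 in enterocyte-like and -0.88 in skeletal muscle-like cells. The last value was 0.018 as the mean of the cells' own CPM, so its direction does not hold. Among classes that met this rule, the high value was in enterocyte-like cells each time. ER stress stood higher in neutrophil-like cells, at 1.13, but with an interval that held 0. Enterocyte-like cells also differed in the epidermal gene icn, at 46034 and 4781 CPM, and in median mitochondrial share, at 0.591% and 3.14%. Unlike make-up of that class in the 2 libraries stays open.

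Of the clusters without a name, which the comparisons within classes did not use, 6 had a UPEC share above the saline share beyond counting error. Cluster 04, at 3.59% and 1.41%, had a lower UPEC share, and cluster 18, at 0.319% and 0.196%, differed within counting error. Cluster 25, led by mmp9, mmp13a and cd44a, held 4.88% of UPEC cells, and cluster 10, led by saa, hamp, ifitm1 and cxcl18b, held 2.79%. Cluster 20, led by s100a1 and ctsl.1, held 5.43%, with a median mitochondrial share of 11.56%, and cluster 09, led by znfl2a, blf and myb, held 5.88%. Cluster 17 held 2.42% and was nearest to neurons, with 100% of the 20 detected neuron markers at a log2 fold of 1 or more. Its leading genes included the hormone genes sst1.2, gip and gh1 and the neuron markers elavl3 and elavl4. Cluster 32, led in part by il13 and il4, held 0.325%, against 0 saline cells. Barcodes over the mitochondrial limit, left out of every comparison but that over all barcodes below, made up 14.9% of UPEC barcodes and 5.37% of saline barcodes.

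Superficial epidermis-like cells had a lower share in UPEC, and 3 technical explanations were weighed. With unnamed clusters joined to the class of their highest markers, the log2 share ratio was -2.56 (-2.69 to -2.44), so cells placed in those clusters could not account for the whole, and whether they belong to the class was not tested. Dilution by erythroid-like cells left -4.16 among the other cells. Removal by the filters left -3.29 over all barcodes, of which 42.7% in saline and 4.37% in UPEC had 5% or more of their UMIs from the markers after thinning to 500 UMIs. Unequal dissociation or dead cell removal and a loss of outer epidermis in infected larvae stay open, each untested.

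The median of the cytokine and chemokine list stood above 0 in the whole library and in all 9 classes. Its interval held 0 at least in neutrophil-like, lymphocyte-like and enterocyte-like cells. In basal epidermis-like cells its 0.19 lay below the median of all genes there, 0.24. Free RNA from phagocytes was argued against as the main source of the UPEC levels. In UPEC, members stood at a median log2 of at least 2.94 above the level that phagocyte markers predict in 8 of 8 classes. Saline levels did not enter that test, so it does not bear directly on the ratios. Free RNA from other sources, such as cluster 25, stays open. A different mix of classes gave 0.85 with equal weight for each of the 9 classes present in both libraries, and few UMIs in the smaller library gave 0.94 over the 22 members with 30 or more saline UMIs, and neither value decides. A response of the whole body to UPEC stays open and untested.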

How the results depend on the processing

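Joined clusters, the limit of 50000 UMIs, shares without erythroid-like cells, scaling within libraries for lists, and members at their bound were tests chosen only after the results were seen. Of 2786 list medians under alternatives, 2651 stayed within the interval of the value in the report, 126 moved outside it and 9 reversed, which was counted where that interval left out 0. For erythroid-like cells, that count took in only the cell cycle list and the cytokine and chemokine list. Of 528 values of named genes, 454 stayed, 71 moved and 3 reversed, of 87 share ratios 64 stayed, 22 moved and 1 reversed, and of 80 shares with a UMI 54 stayed and 26 moved. No paired analysis was possible because each group had 1 library, which also ruled out leaving a library out. Neutrophil-like cells with at least 500 genes were not run, since under 20 saline cells remained. Except where a setting's construction shows it, the cause was not tested.

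The log2 share ratio of superficial epidermis-like cells was -3.84 at 10% mitochondrial UMIs, -2.49 with genes scaled within each library, -5.78 with UPEC cells drawn down, -2.56 with unnamed clusters joined and -4.16 without erythroid-like cells. That of erythroid-like cells was 2.27 at 500 genes, 1.21 with doublets kept, 2.09 at Leiden resolution 2, 1.80 with scaling within libraries and 0.83 with no barcode over 50000 UMIs. Without erythroid-like cells, lymphocyte-like cells stood at 1.25, chondrocyte-like cells reversed to 0.13, and fibroblast-like cells, whose interval held 0, turned to 0.42.

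With each class weighted equally, whole-library medians were 1.65 for acute phase, 1.68 for complement and 0.17 for antibacterial effectors, and krt1-19d reversed to 2.04, while 17 of the 20 named genes moved and 2 stayed. That setting leaves out goblet or mucous-like cells, which held 99.3% of the saline UMIs of krt1-19d, and hepatocyte-like cells, so its values are of other classes. The erythroid-like cell cycle median was -3.36 at 500 genes, -3.13 with no barcode over 50000 UMIs, 0.67 (reversed) at Leiden resolution 2, 0.56 (reversed) with scaling within libraries, -0.90 with clusters joined, -2.03 with median-of-ratios scaling and -1.996 as the mean of the cells' own CPM. In superficial epidermis-like cells it was 1.86 at 10% mitochondrial UMIs, 1.84 with doublets kept, 2.07 with scaling within libraries, 1.71 as the mean of cells and 1.53 without free-RNA members. In neutrophil-like cells it was 0.94 with scaling within libraries, 1.13 as the mean of cells and 1.27 with members at their bound. As the mean of cells, il1b and cebpb reversed there to -0.038 and -0.16, and the skeletal muscle-like cell cycle median to 0.018.

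Further reversals were small in value. In superficial epidermis-like cells, immediate early genes stood at -0.043 and nuclear oxidative phosphorylation at -0.13 with median-of-ratios scaling, and JAK-STAT and SOCS at -0.089 as the mean of cells. In basal epidermis-like cells, tissue repair stood at -0.13 with clusters joined and ribosomal proteins at -0.093 with median-of-ratios scaling. Lipid and lipoprotein genes in skeletal muscle-like cells stood at -0.24 without free-RNA members. Depth limited the neutrophil-like class most, where the saline sums held 138231 UMIs.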

Other observations

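Both tests of short transcripts were chosen only after the result was seen.

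Some immune genes also differed in classes where they were not among the named ones. The antiviral regulator irf7 had a log2 ratio of -1.41 (-1.85 to -0.90) in neutrophil-like cells. The lysosomal thioesterase ppt1 stood lower in UPEC in enterocyte-like (-2.71), basal epidermis-like (-2.16), chondrocyte-like (-2.01) and lymphocyte-like cells (-1.55). The lysozyme-like gene lygl1 stood at 41.4 and 176 CPM in superficial epidermis-like cells.

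Ribosomal protein genes did not share 1 ratio, and their pattern was alike in every class. In the whole libraries rpl26 stood at -2.50, rpl38 at -1.79, rps29 at -1.61 and rpl29 at -1.52, and 7 of 81 such genes lay below -1 in each of the 9 classes while 25 lay above 0 in each. The median Spearman correlation between classes was 0.90 over 36 pairs. Of the mitochondrial genes, mt-atp8 (-2.74), mt-nd4l (-2.19), mt-nd6 (-1.79) and mt-nd3 (-1.11), those with the shortest products, lay below the others in all 9 classes, by a median of -2.34. The correlation restates that the pattern is alike in every class, the mitochondrial genes were picked after their values were seen, and transcript lengths were not used here. A short product also need not mean a short transcript, so the mitochondrial genes cannot decide on transcript length. An effect of the libraries on short transcripts therefore stays open, and a biological cause was not tested.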
